A study of Mus musculus with 52 samples.

How the data were processed

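RNA of bone marrow stromal cell cultures was hybridised to Affymetrix Mouse Gene 2.0 ST arrays, 52 in all. Per the labels, cells of 2 to 4 female mice aged 8 weeks were pooled, osteoinductive medium began 7 days after plating, and a pool of animals made up 1 experiment. The deposited table holds log2 values for 41345 probe sets, made with R 3.3.1 and oligo per the submitters' processing notes. The steps of normalization and background correction are not given in the sources used here, nor is the model the submitters fitted. Array medians and quartiles nearly coincided between arrays, and no 2 arrays were identical.

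Of the probe sets, 23521 carried 1 gene, 1814 carried several and 16010 were unnamed; only the first kind was used, for 22180 genes. Where a gene had several probe sets (1082 genes), the one with the highest mean over all arrays stood for it. A gene was tested if at least 4 of the 52 arrays lay above the median of the table, 4.05, which left 14911 genes and set aside 7269. Groups were compared with limma (group means, all 52 arrays in a single fit, 39 residual degrees of freedom, moderated statistics with 3.45 prior degrees of freedom, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. SEs are limma's, with the spread pooled over all 13 groups. Each chemical was compared with vehicle of the same day, with the other day's difference (interaction) and with other chemicals, and vehicle with naive cells.

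Arrays of a pool share animals, so a fit with the pool as replicate block (36 residual degrees of freedom) stands beside the unblocked one wherever it changed a call or moved a count by over 1.5 times. With group means removed, 45 of 52 arrays correlated best with their own pool (median 0.253). Of 92 same-pool pairs, 74 exceeded 0.1. The next-best pool mostly paired 12 with 15 and 19 with 20.

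The 31 gene lists were adipocyte, thermogenic, fatty acid oxidation, lipogenesis, cholesterol synthesis, LXR target, retinoid target, peroxisome, respiratory chain, osteoblast, osteocyte, osteoclast, matrix, chondrocyte, stromal progenitor, smooth muscle, endothelial, macrophage, neutrophil, B cell, T and NK cell, erythroid, megakaryocyte, mast cell and basophil, cell cycle, glucocorticoid, ER stress, NRF2, xenobiotic, interferon and inflammation. They were tested with camera (preset correlation 0.01, adjusted over lists), with an estimated correlation and fry beside it. Counts adjusted over the list alone stand beside those over all genes, and list scores are means of gene-centred log2 values. Lists share members, so they are not independent. The genes named in a comparison were the 5 largest rises and 5 largest falls among calls that had the same sign in 4 of 4 pools (passing over gene models without a regular symbol), up to 4 members of a list with the smallest adjusted p, and 25 key genes. List members named where 2 chemicals are compared were chosen after their values were seen, as was the choice among the genes so ranked. The groups, comparisons, lists and rule were fixed before the data were examined.

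On simulated data, with 200 genes changed in Rosi at day 1, limma recovered 56% at a log2 change of 0.5, 88% at 1 and 100% at 1.5 and 2, with 5.49% of 182 calls among unchanged genes. Alternatives tried were the replicate block, only the arrays compared, cyclic loess between arrays, the mean of probe sets, no filter, a stricter filter (75th percentile of the table, 6.34), each pool left out, vehicle arrays split 2 and 2 and 2 fits chosen after seeing the data. R 4.3.3, limma 3.58.1, data.table (1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used. No genome positions were used here.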

Results

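Gene expression was measured on Affymetrix Mouse Gene 2.0 ST arrays in primary bone marrow multipotent stromal cell cultures from female C57BL/6J mice, grown in osteoinductive medium. The 52 arrays fell into 13 groups of 4: a naive group harvested before induction, and vehicle (DMSO), Rosi, LG268, TBT, TPhP and MEHP groups harvested after 1 and 4 days. Rosi (rosiglitazone, 100 nM) is an agonist of PPARγ, the nuclear receptor that drives fat cell formation, and LG268 (LG100268, 100 nM) is an agonist of RXR, the partner of PPARγ and of LXR. TBT (tributyltin, 80 nM) is an organotin, TPhP (triphenyl phosphate) a flame retardant, and MEHP (mono-2-ethylhexyl phthalate) a phthalate metabolite. The labels do not give the doses of TPhP and MEHP. Each group held 1 array of each of the numbers 12, 15, 19 and 20 in the titles, read here as 4 pools of animals. Array medians ran from 3.97 to 4.15 on the log2 scale, and the number of arrays limits the precision. After the filter on low values, 14911 genes were tested. Values after gene symbols are log2 differences ± SE between groups of 4 arrays; where † follows, at least 2 of 4 arrays of the lower group lay under 4.05, near background, and the size is uncertain. A gene is said to have risen or fallen only where limma's adjusted p was under 0.05, and genes so named moved the same way in 4 of 4 pools unless a number of pools is given. A list's camera call held with an estimated correlation between genes unless an adjusted p for it is given. Runx2 and Spp1 were not analysed here: no probe set used carried the symbol.

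Vehicle against naive cells, first at day 1, cannot tell medium, DMSO and time in culture apart. Genes of sterol synthesis rose together, among them Mvk (0.94 ± 0.11), mevalonate kinase, Nsdhl (1.40 ± 0.19), Msmo1 (0.84 ± 0.11) and Fdft1 (0.96 ± 0.15), squalene synthase. 17 of 19 cholesterol synthesis genes rose (18 adjusted over the list alone, camera adjusted p = 3.62e-16, adjusted p = 0.131 with an estimated correlation). Targets of the glucocorticoid receptor, for which the medium holds dexamethasone, also rose, as in Fkbp5 (2.00 ± 0.21), Zbtb16 (1.81 ± 0.31), Per1 (1.26 ± 0.11) and Tsc22d3 (1.06 ± 0.15). 8 of 15 glucocorticoid genes rose (10 adjusted over the list alone, camera adjusted p = 7.53e-08, adjusted p = 0.105 with an estimated correlation). The largest rises were Lyve1 (4.52 ± 0.75), a hyaluronan receptor, Sult1a1 (2.81 ± 0.39), a sulfotransferase, Cd163 (2.26 ± 0.39), a macrophage scavenger receptor, P2rx2 (2.17 ± 0.39) and Hspb7 (2.17 ± 0.37). The largest falls were Clec7a (-2.31 ± 0.62), a receptor for fungal glucans, Itgax (-2.21 ± 0.73), an integrin of dendritic cells, Tnip3 (-2.13 ± 0.40), Atf3 (-2.05 ± 0.57), a stress-response factor, and Mamdc2 (-1.96 ± 0.39). In all, 1918 genes rose and 724 fell, against 1279 and 1057 after cyclic loess between arrays. The total was 926 without pool 19 and 868 without pool 20. Leaving out arrays brought the adjusted p past the threshold for Clec7a (0.0904 without pool 20), Itgax (0.166, 0.128 and 0.127 without pools 20, 15 and 19) and Atf3 (0.0935, 0.075 and 0.0739 without pools 20, 15 and 19).

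After 4 days of induction with vehicle, bone-forming genes were higher than in naive cells. These included Dmp1 (4.20 ± 0.92†), an osteocyte matrix protein, Ibsp (2.97 ± 0.62), bone sialoprotein, Ifitm5 (2.28 ± 0.31†), an osteoblast membrane protein, Omd (2.55 ± 0.51) and Sgms2 (1.30 ± 0.21). 7 of 16 osteoblast genes rose and 0 fell (8 and 1 adjusted over the list alone, median 0.61, camera adjusted p = 0.0399, adjusted p = 0.889 with an estimated correlation). Osteoclast genes such as Ctsk (1.84 ± 0.28), cathepsin K, and Acp5 (1.75 ± 0.26), the acid phosphatase of osteoclasts, rose as well. 8 of 14 osteoclast genes rose and 1 fell (8 and 1 adjusted over the list alone, median 0.65, camera adjusted p = 0.052, and 0.0338 with the replicate block). Glucocorticoid receptor targets stayed high, with Fkbp5 (2.09 ± 0.21) and Klf9 (1.39 ± 0.15). 13 of 15 glucocorticoid genes rose (13 adjusted over the list alone, camera adjusted p = 8.06e-10). Rises were greatest in Lyve1 (6.08 ± 0.75), Serpina3n (4.26 ± 0.86†), a protease inhibitor, Dmp1, Itgbl1 (3.42 ± 0.55†) and C1qtnf3 (3.42 ± 0.56). B lymphocyte genes fell, led by Ms4a1 (-2.88 ± 0.44†), which encodes CD20, and Cd79a (-2.10 ± 0.36). 7 of 9 B cell genes fell (7 adjusted over the list alone, camera adjusted p = 1.26e-05, adjusted p = 0.14 with an estimated correlation). The other large falls were Itgax (-2.85 ± 0.73†), Clec4b1 (-2.47 ± 0.38†), Fcmr (-2.39 ± 0.39) and Ccr2 (-2.18 ± 0.40), a monocyte chemokine receptor. Contractile genes fell, among them Tagln (-1.58 ± 0.24) and Cnn1 (-1.38 ± 0.36). 6 of 10 smooth muscle genes fell (6 adjusted over the list alone, camera adjusted p = 0.000311, adjusted p = 0.476 with an estimated correlation). Detoxification genes rose, with Ephx1 (0.89 ± 0.12), an epoxide hydrolase, and Tiparp (0.93 ± 0.17). 5 of 7 xenobiotic genes rose (6 adjusted over the list alone, camera adjusted p = 0.00203, adjusted p = 0.0581 with an estimated correlation). In all, 2596 genes rose and 1712 fell. Counted otherwise, the total was 2093 with only the arrays of the groups compared, 2464 without pool 19 and 2433 without pool 20. The adjusted p passed the threshold with arrays left out for the osteoblast list (0.23 and 0.181 without pools 20 and 19).

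Between day 1 and day 4 of vehicle, osteoclast genes rose, such as Dcstamp (1.50 ± 0.18) and Ocstamp (1.59 ± 0.22), which act in cell fusion, and Car2 (1.43 ± 0.25), a carbonic anhydrase. 8 of 14 osteoclast genes rose and 1 fell (8 and 1 adjusted over the list alone, median 1.02, camera adjusted p = 6.32e-07). Contractile genes fell, with Cnn1 (-2.19 ± 0.36), Tagln (-1.66 ± 0.24), Actg2 (-1.69 ± 0.29) and Myocd (-1.38 ± 0.19), their transcriptional coactivator. 9 of 10 smooth muscle genes fell (9 adjusted over the list alone, camera adjusted p = 7.98e-12). Cell division genes fell, with Cenpe (-0.87 ± 0.16) and Birc5 (-0.94 ± 0.18). 15 of 24 cell cycle genes fell (17 adjusted over the list alone, camera adjusted p = 8.41e-12, adjusted p = 0.303 with an estimated correlation). Rising most were Serpina3n (4.05 ± 0.86†), Dmp1 (3.42 ± 0.92), Mmp9 (3.10 ± 0.60), a matrix protease of osteoclasts, Gdpd2 (2.78 ± 0.54) and Bmp3 (2.61 ± 0.40†). The largest falls also held Gzmd (-2.46 ± 0.46), a granzyme, Cx3cr1 (-1.93 ± 0.36), a monocyte receptor, and Ms4a1 (-1.87 ± 0.44†). Fat cell genes also rose in vehicle, with Adipoq (2.52 ± 0.33) and Gpd1 (2.15 ± 0.51). 7 of 25 adipocyte genes rose and 2 fell (12 and 3 adjusted over the list alone, median 0.55, camera adjusted p = 0.000248, adjusted p = 0.514 with an estimated correlation). 2 of 9 osteocyte genes rose (5 adjusted over the list alone, camera adjusted p = 0.00222, adjusted p = 0.0933 with an estimated correlation). 0 of 11 T and NK cell genes passed limma's test (0 higher and 0 lower adjusted over the list alone, median 0.83, camera adjusted p = 0.00468, adjusted p = 0.514 with an estimated correlation). In all, 686 genes rose and 1236 fell, against 907 and 978 after cyclic loess between arrays. That total became 568 with only the arrays of the groups compared, 785 without pool 19 and 834 without pool 20. Calls were lost with arrays left out, at the adjusted p given, for Dmp1 (0.0716 and 0.0537 without pools 20 and 12), Ms4a1 (0.0602 without pool 15), Gpd1 (0.0649 without pool 15) and the T and NK cell list (0.268 without pool 12).

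**Figure D1:**
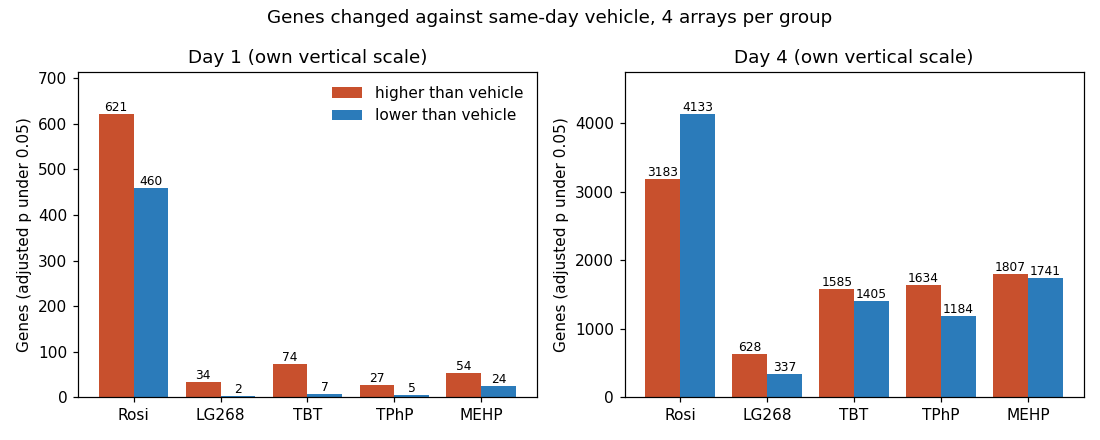
Number of genes higher (red) and lower (blue) than in vehicle of the same day, by limma at adjusted p under 0.05, for each chemical with 4 arrays per group; the left panel is day 1 and the right panel day 4, each on its own vertical scale. Rosi changed 1081 genes at day 1 and 7316 at day 4, and LG268 changed 36 and 965. The fit pools the spread of both days, so the counts are not strictly comparable between days.

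Rosi against vehicle at day 1 asks what a PPARγ agonist did in cells held in bone-forming medium. Fat cell genes rose strongly, among them Plin1 (4.73 ± 0.42) and Cidec (4.67 ± 0.80†), lipid droplet proteins, Fabp4 (2.62 ± 0.20), a fatty acid carrier, Adipoq (3.07 ± 0.33), Aqp7 (3.49 ± 0.24), a glycerol channel, and Trarg1 (2.60 ± 0.20). 21 of 25 adipocyte genes rose (22 adjusted over the list alone, camera adjusted p = 7.42e-47). The mean log2 value of Fabp4 was 9.52 ± 0.27 (SD, n = 4) in vehicle and 12.14 ± 0.10 with Rosi. Fatty acid oxidation genes rose, with Angptl4 (2.98 ± 0.18), an inhibitor of lipoprotein lipase, Acaa2 (1.18 ± 0.17), Ech1 (0.92 ± 0.13) and Acadm (0.96 ± 0.17). 14 of 24 fatty acid oxidation genes rose (17 adjusted over the list alone, camera adjusted p = 2e-15). Greatest rises came from Car3 (4.74 ± 0.63), a carbonic anhydrase of fat, Plin1, Cidec, Gpd1 (4.58 ± 0.51), glycerol-3-phosphate dehydrogenase, and Lgals12 (4.53 ± 0.37†), a galectin of fat cells. Falling most were Ptgs2 (-2.14 ± 0.44), which encodes cyclooxygenase 2, Map3k7cl (-2.14 ± 0.20), Hspb7 (-2.10 ± 0.37), Tnfrsf11b (-2.09 ± 0.32), the decoy receptor osteoprotegerin, and Lgr5 (-1.93 ± 0.43†). Contractile genes fell, with Myocd (-1.44 ± 0.19) and Lmod1 (-1.15 ± 0.22). 6 of 10 smooth muscle genes fell (10 adjusted over the list alone, camera adjusted p = 2.79e-10, adjusted p = 0.0588 with an estimated correlation). Peroxisomal genes rose, with Pex16 (1.38 ± 0.20) and Scp2 (1.24 ± 0.18). 8 of 18 peroxisome genes rose (11 adjusted over the list alone, camera adjusted p = 1.82e-10, adjusted p = 0.148 with an estimated correlation). Of the cholesterol export receptor's targets, 6 of 17 LXR target genes rose (6 adjusted over the list alone, camera adjusted p = 0.00291, adjusted p = 0.0666 with an estimated correlation), with Abcg1 (1.63 ± 0.24) and Nr1h3 (1.00 ± 0.15), LXRα itself, higher and Abca1 (0.37 ± 0.16, adjusted p = 0.195, or 0.0353 with the replicate block) not called. Bone-forming genes Smpd3 (-1.77 ± 0.32), Bmp4 (-1.27 ± 0.25) and Sp7 (-1.58 ± 0.44), the osteoblast factor osterix, fell. 3 of 16 osteoblast genes fell (4 adjusted over the list alone, camera adjusted p = 0.00154, adjusted p = 0.819 with an estimated correlation). In all, 621 genes rose and 460 fell. This count was 585 without pool 19 and 430 without pool 20. Fewer arrays ended the call, at the adjusted p given, of Lgr5 (0.0759 without pool 20) and Sp7 (0.212 and 0.0766 without pools 20 and 19).

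LG268 at day 1 asks what an RXR agonist did in the same medium. The cholesterol exporters Abca1 (2.11 ± 0.16) and Abcg1 (2.09 ± 0.24) and other LXR targets, Mylip (0.80 ± 0.12), which degrades the LDL receptor, and Lpcat3 (0.74 ± 0.13), rose. 8 of 17 LXR target genes rose (12 adjusted over the list alone, camera adjusted p = 4.78e-49). Abca1 stood at 8.64 ± 0.44 (SD, n = 4) in vehicle and 10.75 ± 0.21 with LG268. Rises were largest for Angptl4 (2.19 ± 0.18), Abca1, Abcg1, Apoc2 (1.88 ± 0.27), an apolipoprotein, and Cyp26b1 (1.56 ± 0.21), which breaks down retinoic acid. The only falls were Ccr3 (-1.30 ± 0.31), an eosinophil chemokine receptor, and Cd300ld3 (-0.91 ± 0.16). 1 of 10 retinoid target genes rose (2 adjusted over the list alone, camera adjusted p = 3.22e-08). Fat cell genes Fabp4 (1.23 ± 0.20), Trarg1 (1.19 ± 0.20) and Lpl (0.56 ± 0.10) rose. 4 of 25 adipocyte genes rose (14 adjusted over the list alone, camera adjusted p = 1.47e-28). The values of 2 others were Plin1 (1.44 ± 0.42, adjusted p = 0.286, or 0.013 with the replicate block) and Cidec (3.14 ± 0.80†, adjusted p = 0.0972, or 0.00201 with the replicate block). Fatty acid oxidation genes Plin2 (1.08 ± 0.17) and Cpt1a (0.93 ± 0.15), the gate of mitochondrial uptake, rose. 3 of 24 fatty acid oxidation genes rose (3 adjusted over the list alone, camera adjusted p = 1.12e-12). For fatty acid synthesis, 3 of 19 lipogenesis genes rose (5 adjusted over the list alone, camera adjusted p = 2.43e-18), including Srebf1 (1.04 ± 0.19), its transcription factor, and Scd1 (1.31 ± 0.28), a desaturase. Values of bone genes were Sp7 (-0.54 ± 0.44, adjusted p = 1), osterix, and Alpl (-0.20 ± 0.27, adjusted p = 1), alkaline phosphatase. In all, 34 genes rose and 2 fell. Other fits gave a total of 68 with the replicate block, 20 without pool 15, 15 without pool 19 and 13 without pool 20. Limma's call ended with fewer arrays, at the adjusted p given, for Ccr3 (0.898, 0.432 and 0.362 without pools 20, 19 and 15), Cd300ld3 (0.0787 without pool 20), Fabp4 (0.0599 without pool 15), Lpl (0.114 without pool 20), Srebf1 (0.114 and 0.0649 without pools 20 and 15) and Scd1 (0.638, 0.292 and 0.0785 without pools 15, 19 and 20).

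TBT at day 1 asks which of these programmes an organotin engaged. It raised LXR targets, with Abca1 (1.89 ± 0.16), Abcg1 (1.88 ± 0.24), Mylip (0.69 ± 0.12) and Pltp (0.74 ± 0.14), a phospholipid carrier. 8 of 17 LXR target genes rose (12 adjusted over the list alone, camera adjusted p = 1.9e-30). Fat cell genes rose too, with Fabp4 (1.63 ± 0.20), Aqp7 (1.85 ± 0.24), Trarg1 (1.87 ± 0.20) and Lpl (0.68 ± 0.10). 9 of 25 adipocyte genes rose (12 adjusted over the list alone, camera adjusted p = 5.57e-24). The largest rises were Angptl4 (2.73 ± 0.18), Car3 (2.63 ± 0.63), Hcar1 (2.29 ± 0.29), the lactate receptor of fat cells, Adamts15 (1.94 ± 0.34) and Abca1. Falls were largest for Ccr3 (-1.36 ± 0.31), Sox9 (-1.18 ± 0.24), the cartilage factor, and Tubb3 (-0.96 ± 0.23). Fatty acid oxidation genes Plin2 (1.28 ± 0.17) and Cpt1a (1.13 ± 0.15) rose. 4 of 24 fatty acid oxidation genes rose (6 adjusted over the list alone, camera adjusted p = 8.73e-15). Of retinoid genes, Cyp26b1 (1.21 ± 0.21) rose. 1 of 10 retinoid target genes rose (1 adjusted over the list alone, camera adjusted p = 0.00348). Values of bone genes were Sp7 (-0.91 ± 0.44, adjusted p = 0.751) and Alpl (-0.27 ± 0.27, adjusted p = 0.999). 0 of 16 osteoblast genes passed limma's test (0 higher and 0 lower adjusted over the list alone, median -0.46, camera adjusted p = 0.00093, adjusted p = 0.676 with an estimated correlation). In all, 74 genes rose and 7 fell. The number of changed genes was 171 with the replicate block, 174 with only the arrays of the groups compared, 47 without pool 15, 37 without pool 19 and 33 without pool 20. Leaving out arrays brought the adjusted p past the threshold for Mylip (0.0871 without pool 15), Pltp (0.15 and 0.0768 without pools 19 and 20), Car3 (0.426 and 0.324 without pools 15 and 19), Adamts15 (0.0905 and 0.0515 without pools 15 and 20), Ccr3 (0.516, 0.225 and 0.117 without pools 20, 19 and 15), Sox9 (0.261 and 0.213 without pools 20 and 19) and Tubb3 (0.503, 0.256 and 0.186 without pools 19, 20 and 15).

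TPhP at day 1 raised a small set of genes, fat cell genes among them. Rises were greatest in Angptl4 (2.03 ± 0.18), Aqp7 (1.97 ± 0.24), Fabp4 (1.69 ± 0.20), Lgals12 (1.67 ± 0.37†) and Adipoq (1.60 ± 0.33). 6 of 25 adipocyte genes rose (14 adjusted over the list alone, camera adjusted p = 5.15e-30). Falls were greatest in Aspn (-1.53 ± 0.35), a matrix proteoglycan, and Scx (-1.08 ± 0.24), the tendon factor. 0 of 17 LXR target genes passed limma's test (2 higher and 0 lower adjusted over the list alone, median 0.22, camera adjusted p = 0.00287, adjusted p = 0.121 with an estimated correlation). The exporters stood at Abca1 (0.27 ± 0.16, adjusted p = 0.952) and Abcg1 (0.90 ± 0.24, adjusted p = 0.107, or 0.00865 with the replicate block). Of fatty acid oxidation genes Angptl4 rose. 1 of 24 fatty acid oxidation genes rose (5 adjusted over the list alone, camera adjusted p = 2.14e-08, adjusted p = 0.229 with an estimated correlation). 0 of 23 macrophage genes passed limma's test (0 higher and 0 lower adjusted over the list alone, median -0.28, camera adjusted p = 2.23e-05, adjusted p = 0.622 with an estimated correlation), and 0 of 15 neutrophil genes passed limma's test (0 higher and 0 lower adjusted over the list alone, median -0.57, camera adjusted p = 0.000141, adjusted p = 0.622 with an estimated correlation). In all, 27 genes rose and 5 fell. The total was 71 with the replicate block, 63 without pool 12, 12 without pool 15, 13 without pool 19 and 8 without pool 20. The adjusted p passed the threshold with arrays left out for Lgals12 (0.665, 0.426 and 0.3 without pools 20, 15 and 19), Adipoq (0.86 and 0.265 without pools 20 and 15), Aspn (0.422, 0.215, 0.213, 0.0898 and 0.301 without pool 19, 15, 20, 12 and the TPhP arrays of pool 12), Scx (0.932, 0.272 and 0.105 without pool 20, 19 and the TPhP arrays of pool 12), the LXR target list (0.0716 without pool 15) and the macrophage list (0.424 and 0.181 without pool 12 and the TPhP arrays of pool 12).

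MEHP at day 1 raised fat cell genes, with Fabp4 (1.87 ± 0.20), Aqp7 (2.09 ± 0.24), Adipoq (1.87 ± 0.33) and Trarg1 (1.77 ± 0.20). 10 of 25 adipocyte genes rose (15 adjusted over the list alone, camera adjusted p = 1.5e-34). Rising most were Car3 (2.94 ± 0.63), Angptl4 (2.21 ± 0.18) and Plin1 (2.17 ± 0.42). The largest falls were Ifi213 (-2.14 ± 0.44†), an interferon-inducible gene, Aspn (-1.74 ± 0.35) and Scx (-1.25 ± 0.24). 0 of 17 interferon genes passed limma's test (0 higher and 9 lower adjusted over the list alone, median -1.05, camera adjusted p = 6.15e-13, adjusted p = 0.197 with an estimated correlation). Their values included Irf7 (-1.40 ± 0.44, adjusted p = 0.199, or 0.0154 with the replicate block) and Usp18 (-1.51 ± 0.52, adjusted p = 0.291, or 0.00732 with the replicate block). The retinoic acid receptor gene Rarb (1.14 ± 0.22†) rose. 1 of 10 retinoid target genes rose (3 adjusted over the list alone, camera adjusted p = 0.00618, adjusted p = 0.0614 with an estimated correlation). Values of the LXR targets were Abca1 (0.19 ± 0.16, adjusted p = 0.925) and Abcg1 (0.50 ± 0.24, adjusted p = 0.629). 1 of 17 LXR target genes rose (1 adjusted over the list alone, camera adjusted p = 0.00954, adjusted p = 0.182 with an estimated correlation). For oxidative stress, 1 of 14 NRF2 genes rose (1 adjusted over the list alone, camera adjusted p = 0.000531, adjusted p = 0.182 with an estimated correlation). In all, 54 genes rose and 24 fell. Counted otherwise, the total was 176 with the replicate block, 190 with only the arrays of the groups compared, 37 without pool 15, 21 without pool 19 and 10 without pool 20. Calls were lost with arrays left out, at the adjusted p given, for Adipoq (0.247 without pool 20), Car3 (0.207, 0.176 and 0.171 without pools 15, 20 and 19), Plin1 (0.176, 0.119 and 0.0633 without pools 20, 15 and 19), Ifi213 (0.176, 0.0866 and 0.0663 without pools 20, 12 and 15), Aspn (0.239, 0.158 and 0.0562 without pools 19, 20 and 15), Scx (0.281 without pool 20), Rarb (0.172 without pool 19) and the LXR target list (0.0535 without pool 19).

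**Figure D2:**
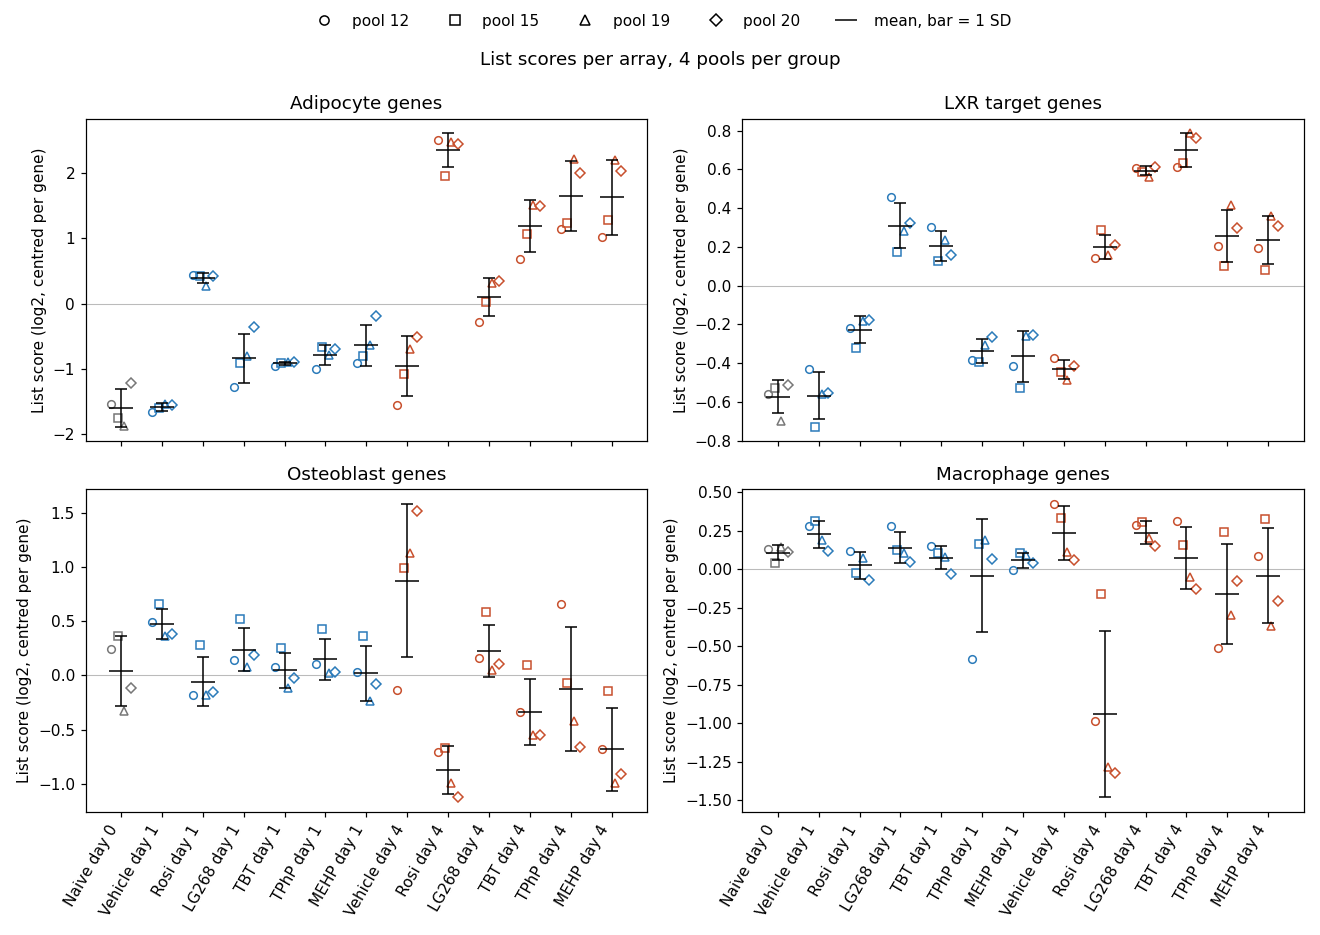
Mean score of 4 gene lists on each array (log2, each gene centred on its mean over the 52 arrays), by group, with 1 symbol per pool and bars for the mean ± 1 SD of 4 arrays. Adipocyte scores with Rosi at day 4 ran from 1.95 to 2.50, above the mean of -0.96 in vehicle of that day.

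After 4 days of Rosi the cultures carried a fat cell profile. Fat cell genes rose, with Plin4 (4.38 ± 0.26), Trarg1 (4.31 ± 0.20), Pnpla2 (2.70 ± 0.19), the first lipase of fat stores, Cidec (5.51 ± 0.80) and Fabp4 (2.31 ± 0.20). 25 of 25 adipocyte genes rose (25 adjusted over the list alone, camera adjusted p = 2.95e-23). Greatest rises came from Sptlc3 (7.33 ± 0.52†), a sphingolipid enzyme, Elovl3 (6.95 ± 0.53†), an elongase of brown fat, Cox8b (6.09 ± 0.51†), a respiratory subunit of brown fat and muscle, Cyp2e1 (5.88 ± 0.32†), a cytochrome P450, and Tmem45b (5.57 ± 0.42†). Thermogenic genes rose, with Ppargc1a (4.65 ± 0.30†), a coactivator of mitochondrial genes, Cox7a1 (3.55 ± 0.31) and Ucp1 (1.02 ± 0.20†, in 3 of 4 pools), the uncoupling protein of brown fat. 11 of 16 thermogenic genes rose and 1 fell (11 and 1 adjusted over the list alone, median 1.06, camera adjusted p = 4.42e-06, adjusted p = 0.135 with an estimated correlation). Fuel-burning groups rose together: 21 of 24 fatty acid oxidation genes rose (21 adjusted over the list alone, camera adjusted p = 1.33e-16), 24 of 24 respiratory chain genes rose (24 adjusted over the list alone, camera adjusted p = 2.21e-20, adjusted p = 0.122 with an estimated correlation), and 18 of 18 peroxisome genes rose (18 adjusted over the list alone, camera adjusted p = 4.99e-14, adjusted p = 0.0996 with an estimated correlation). Examples were Acadl (2.14 ± 0.16), Ndufs1 (1.72 ± 0.14), Cyc1 (2.14 ± 0.18) and Pex16 (2.78 ± 0.20). Fatty acid synthesis genes rose, with Mlxipl (3.29 ± 0.26), Acss2 (3.55 ± 0.29) and Srebf1 (2.27 ± 0.19). 15 of 19 lipogenesis genes rose (16 adjusted over the list alone, camera adjusted p = 2.47e-12, adjusted p = 0.135 with an estimated correlation). Genes of the amino acid and unfolded protein response rose, with Cth (3.71 ± 0.47), Asns (1.53 ± 0.25) and Dnajb9 (1.74 ± 0.14). 12 of 16 ER stress genes rose (12 adjusted over the list alone, camera adjusted p = 0.000104, adjusted p = 0.234 with an estimated correlation). Bone-forming genes fell, with Alpl (-2.29 ± 0.27), Pth1r (-2.55 ± 0.30), the parathyroid hormone receptor, Sp7 (-2.73 ± 0.44) and Col1a2 (-1.44 ± 0.16). 14 of 16 osteoblast genes fell (14 adjusted over the list alone, camera adjusted p = 1.69e-06, adjusted p = 0.234 with an estimated correlation). Falling most were C1qtnf3 (-3.68 ± 0.56), Panx3 (-3.47 ± 0.74), a channel of osteoblasts, Omd (-3.36 ± 0.51), osteomodulin, P2rx2 (-3.12 ± 0.39†) and Cd5l (-2.94 ± 0.65), a macrophage product. Cell cycle genes fell, as with Plk1 (-1.60 ± 0.16) and Cdk1 (-1.26 ± 0.14). 24 of 24 cell cycle genes fell (24 adjusted over the list alone, camera adjusted p = 9.89e-13, adjusted p = 0.184 with an estimated correlation). Macrophage genes fell, with Lyz2 (-1.02 ± 0.11), Itgam (-1.52 ± 0.21) and Fcer1g (-1.15 ± 0.14). 21 of 23 macrophage genes fell (22 adjusted over the list alone, camera adjusted p = 1.96e-08, adjusted p = 0.231 with an estimated correlation). Osteoclast genes mostly fell, led by Ctsk (-2.38 ± 0.28), while Car2 (1.72 ± 0.25) rose. 1 of 14 osteoclast genes rose and 9 fell (1 and 11 adjusted over the list alone, median -0.92, camera adjusted p = 0.0106, adjusted p = 0.14 with an estimated correlation). In all, 3183 genes rose and 4133 fell. On the Rosi array of pool 15 the adipocyte score was 1.95, against 2.44 to 2.50 on the other 3.

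With LG268 at day 4, LXR targets and fatty acid synthesis genes rose, including Abca1 (2.18 ± 0.16), Srebf1 (1.54 ± 0.19), Apoc1 (1.98 ± 0.27), an apolipoprotein, Fasn (1.70 ± 0.27), fatty acid synthase, and Scd1 (1.84 ± 0.28). 14 of 17 LXR target genes rose (14 adjusted over the list alone, camera adjusted p = 9.36e-24), and 14 of 19 lipogenesis genes rose (14 adjusted over the list alone, camera adjusted p = 1.71e-17). Fat cell genes rose, with Fabp4 (1.53 ± 0.20), Plin1 (2.03 ± 0.42), Trarg1 (2.18 ± 0.20) and Lpl (0.77 ± 0.10). 15 of 25 adipocyte genes rose (21 adjusted over the list alone, camera adjusted p = 8.63e-21). Rises were largest for Moxd1 (2.96 ± 0.31†), a monooxygenase, Hcar1 (2.90 ± 0.29), Adamts15 (2.90 ± 0.34), Cldn11 (2.89 ± 0.25), a claudin, and Thrsp (2.88 ± 0.71), a lipid synthesis factor. Falls were largest for Panx3 (-2.90 ± 0.74), Serpina3n (-2.73 ± 0.86) and Clec4n (-2.23 ± 0.34), a C-type lectin of myeloid cells. Neutrophil genes fell, among them Mpo (-1.63 ± 0.44), myeloperoxidase. 9 of 15 neutrophil genes fell (13 adjusted over the list alone, camera adjusted p = 2.16e-09, adjusted p = 0.198 with an estimated correlation). Osteoclast genes fell, as with Ctsk (-1.22 ± 0.28). 3 of 14 osteoclast genes fell (5 adjusted over the list alone, camera adjusted p = 0.000273). The bone gene Ifitm5 (-1.73 ± 0.31) fell. 5 of 16 osteoblast genes fell (8 adjusted over the list alone, camera adjusted p = 2.53e-05, adjusted p = 0.327 with an estimated correlation). Values of bone regulators were Sp7 (-1.30 ± 0.44, adjusted p = 0.0677, or 0.0256 with the replicate block) and Alpl (-0.68 ± 0.27, adjusted p = 0.13). Stromal genes rose, with Il7 (1.29 ± 0.22) and Vcam1 (1.02 ± 0.19). 6 of 14 stromal progenitor genes rose (9 adjusted over the list alone, camera adjusted p = 1.52e-07, adjusted p = 0.121 with an estimated correlation). In all, 628 genes rose and 337 fell. That total became 1590 with the replicate block, 369 with only the arrays of the groups compared, 454 without pool 15, 482 without pool 19 and 367 without pool 20. Fewer arrays ended the call, at the adjusted p given, of Thrsp (0.0738 and 0.0661 without pools 19 and 15), Panx3 (0.22 and 0.143 without pools 20 and 19), Serpina3n (0.307, 0.134, 0.0862 and 0.076 without pools 12, 15, 20 and 19), Mpo (0.208, 0.0872 and 0.0863 without pools 20, 15 and 19) and Ctsk (0.102 without pool 20).

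TBT at day 4 raised fat cell genes and LXR targets. The former held Plin1 (3.83 ± 0.42), Cidec (4.18 ± 0.80), Fabp4 (2.15 ± 0.20), Plin4 (3.10 ± 0.26) and Aqp7 (2.91 ± 0.24). 22 of 25 adipocyte genes rose (23 adjusted over the list alone, camera adjusted p = 1.62e-35). The latter held Abca1 (1.80 ± 0.16) and, also of lipogenesis, Fasn (2.75 ± 0.27) and Srebf1 (1.96 ± 0.19). 14 of 17 LXR target genes rose and 1 fell (14 and 1 adjusted over the list alone, median 1.14, camera adjusted p = 6.04e-16). Abca1 stood at 8.77 ± 0.27 (SD, n = 4) in vehicle and 10.57 ± 0.14 with TBT. The largest rises were Thrsp (4.32 ± 0.71), Cidec, Hcar1 (4.16 ± 0.29), Lgals12 (3.96 ± 0.37) and Plin1. Falls were greatest in Panx3 (-3.51 ± 0.74), Tnn (-2.94 ± 0.44), tenascin N, C1qtnf3 (-2.81 ± 0.56), Slc13a5 (-2.59 ± 0.58), a citrate carrier, and Ibsp (-2.52 ± 0.62). Bone-forming genes fell, with Alpl (-1.89 ± 0.27), Smpd3 (-1.98 ± 0.32) and Pth1r (-1.83 ± 0.30). 13 of 16 osteoblast genes fell (13 adjusted over the list alone, camera adjusted p = 8.54e-10, adjusted p = 0.145 with an estimated correlation). Fuel-burning and lipid synthesis groups rose, with Acadl (1.30 ± 0.16), Sdha (0.61 ± 0.11) and Mlxipl (2.75 ± 0.26). 21 of 24 fatty acid oxidation genes rose and 0 fell (21 and 1 adjusted over the list alone, median 0.95, camera adjusted p = 3.29e-20), 18 of 24 respiratory chain genes rose (23 adjusted over the list alone, camera adjusted p = 1.38e-12, adjusted p = 0.205 with an estimated correlation), and 17 of 19 lipogenesis genes rose (18 adjusted over the list alone, camera adjusted p = 1.59e-25). Endothelial genes rose, with Kdr (1.80 ± 0.45), the VEGF receptor, Robo4 (1.64 ± 0.34) and Emcn (1.50 ± 0.36). 10 of 14 endothelial genes rose (11 adjusted over the list alone, camera adjusted p = 2.42e-06, adjusted p = 0.257 with an estimated correlation). Cell cycle genes fell, as with Aurka (-0.73 ± 0.15). 20 of 24 cell cycle genes fell (24 adjusted over the list alone, camera adjusted p = 3.58e-11, adjusted p = 0.205 with an estimated correlation). In all, 1585 genes rose and 1405 fell. This count was 1676 with only the arrays of the groups compared, 1497 without pool 19 and 1306 without pool 20. Limma's call ended with fewer arrays, at the adjusted p given, for Slc13a5 (0.0733 without pool 20) and Ibsp (0.0838 without pool 20).

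TPhP at day 4 raised every adipocyte gene measured, with Plin1 (4.23 ± 0.42), Cidec (4.55 ± 0.80), Fabp4 (2.18 ± 0.20), Plin4 (3.31 ± 0.26) and Pparg (1.23 ± 0.14) itself. 25 of 25 adipocyte genes rose (25 adjusted over the list alone, camera adjusted p = 3.98e-46). Rises were greatest in Cidec, Lgals12 (4.33 ± 0.37), Plin1, Aldh1a7 (4.20 ± 0.50), an aldehyde dehydrogenase, and Thrsp (4.19 ± 0.71). The largest falls were C1qtnf3 (-3.40 ± 0.56), Aspn (-2.54 ± 0.35), Tnn (-2.37 ± 0.44), Cthrc1 (-2.10 ± 0.33), a matrix protein, and Ctsk (-2.06 ± 0.28). Energy genes rose, with Acadm (1.43 ± 0.17), Uqcrc2 (0.94 ± 0.14) and Pex11a (1.76 ± 0.21). 24 of 24 respiratory chain genes rose (24 adjusted over the list alone, camera adjusted p = 1.46e-22, adjusted p = 0.0515 with an estimated correlation), 19 of 24 fatty acid oxidation genes rose (19 adjusted over the list alone, camera adjusted p = 3.75e-19), and 15 of 18 peroxisome genes rose (16 adjusted over the list alone, camera adjusted p = 3.4e-16). Lipid synthesis genes rose, with Dgat2 (3.81 ± 0.38), the last step of triglyceride synthesis, and Fasn (2.87 ± 0.27). 16 of 19 lipogenesis genes rose (17 adjusted over the list alone, camera adjusted p = 8.77e-24). 10 of 17 LXR target genes rose and 1 fell (10 and 1 adjusted over the list alone, median 0.61, camera adjusted p = 9.26e-06), with Abca1 (0.61 ± 0.16). Bone-forming and matrix genes fell, with Col1a1 (-1.09 ± 0.18, in 3 of 4 pools), Alpl (-1.38 ± 0.27, in 3 of 4 pools), Col3a1 (-1.29 ± 0.18) and Dcn (-1.86 ± 0.28), decorin. 11 of 16 osteoblast genes fell (14 adjusted over the list alone, camera adjusted p = 8.78e-08, adjusted p = 0.217 with an estimated correlation), and 3 of 23 matrix genes rose and 14 fell (4 and 16 adjusted over the list alone, median -0.63, camera adjusted p = 3.2e-05, adjusted p = 0.311 with an estimated correlation). In all, 1634 genes rose and 1184 fell, and without the TPhP arrays of pool 12 the total was 3281. Other fits gave a total of 816 with only the arrays of the groups compared, 1082 without pool 19 and 1226 without pool 20. Leaving out arrays brought the adjusted p past the threshold for Abca1 (0.136 and 0.107 without pools 19 and 20) and Alpl (0.0894 without pool 20).

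MEHP at day 4 likewise raised all 25 adipocyte genes, with Cidec (4.72 ± 0.80), Plin1 (4.20 ± 0.42), Fabp4 (2.18 ± 0.20), Trarg1 (3.08 ± 0.20) and Plin4 (3.14 ± 0.26). 25 of 25 adipocyte genes rose (25 adjusted over the list alone, camera adjusted p = 2.47e-40). Rising most were Sptlc3 (5.03 ± 0.52†), Cidec, Thrsp (4.45 ± 0.71), Aldh1a7 (4.42 ± 0.50) and Cox8b (4.34 ± 0.51†). Falling most were C1qtnf3 (-3.67 ± 0.56), Panx3 (-3.34 ± 0.74), Tnn (-3.28 ± 0.44), Slc13a5 (-3.13 ± 0.58†) and Ndnf (-3.00 ± 0.49), a secreted factor. Bone-forming genes fell, with Alpl (-2.29 ± 0.27), Sp7 (-2.68 ± 0.44), Pth1r (-2.14 ± 0.30) and Col1a1 (-1.40 ± 0.18). 14 of 16 osteoblast genes fell (14 adjusted over the list alone, camera adjusted p = 1.74e-12, adjusted p = 0.0678 with an estimated correlation). The osteoblast factor Sp7 stood at 8.24 ± 1.09 (SD, n = 4) in vehicle and 5.57 ± 0.87 with MEHP. Energy genes rose, with Acadm (1.61 ± 0.17), Ucp3 (2.32 ± 0.25†) and Cycs (1.11 ± 0.15), cytochrome c. 20 of 24 fatty acid oxidation genes rose (20 adjusted over the list alone, camera adjusted p = 9.21e-23), and 24 of 24 respiratory chain genes rose (24 adjusted over the list alone, camera adjusted p = 1.12e-22, adjusted p = 0.0591 with an estimated correlation). Thermogenic genes rose, with Ppargc1a (2.85 ± 0.30†) and Elovl3 (3.12 ± 0.53†). 9 of 16 thermogenic genes rose (10 adjusted over the list alone, camera adjusted p = 1.12e-05, adjusted p = 0.121 with an estimated correlation). 9 of 17 LXR target genes rose and 1 fell (10 and 2 adjusted over the list alone, median 0.60, camera adjusted p = 2.66e-05), with Srebf1 (1.68 ± 0.19) and Abca1 (0.80 ± 0.16). In all, 1807 genes rose and 1741 fell. The number of changed genes was 1048 with only the arrays of the groups compared, 1626 without pool 19 and 1503 without pool 20.

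**Figure D3:**
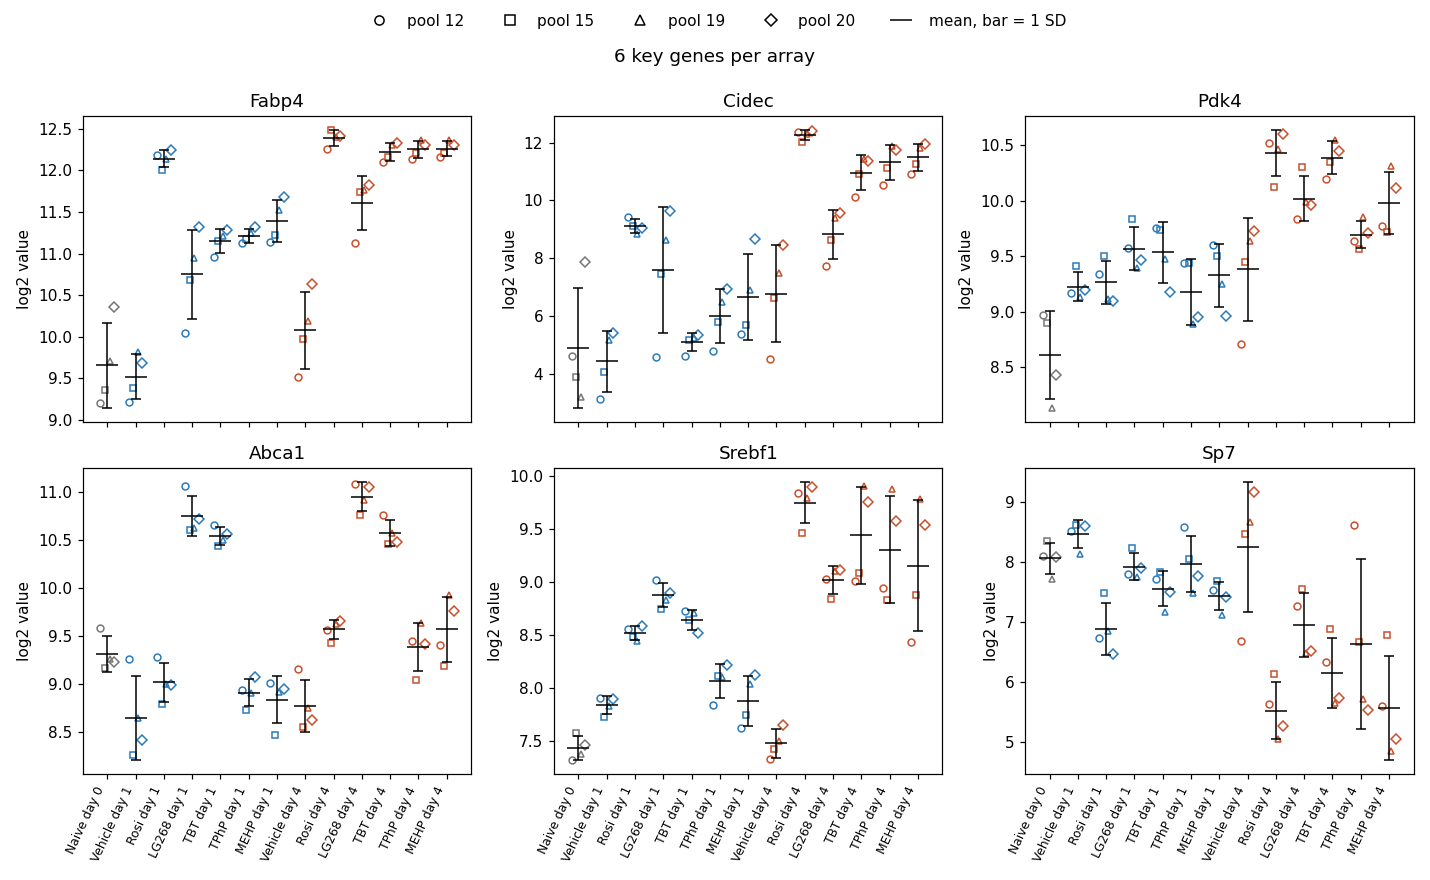
Log2 values of Fabp4, Cidec, Pdk4, Abca1, Srebf1 and Sp7 on each array by group, with 1 symbol per pool and bars for the mean ± 1 SD of 4 arrays. At day 1 Abca1 was 10.75 ± 0.21 with LG268 and 10.54 ± 0.09 with TBT, against 8.64 ± 0.44 in vehicle, while Fabp4 was 12.14 ± 0.10 with Rosi.

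Direct comparisons ask where the chemicals parted at the same day, at doses that differ (Rosi and LG268 100 nM, TBT 80 nM) or that the labels do not give (TPhP, MEHP). At day 1, TBT gave higher LXR targets than Rosi, with Abca1 (1.52 ± 0.16), and higher Apoc2 (1.98 ± 0.27) and Cyp26b1 (1.75 ± 0.21). 4 of 17 LXR target genes were higher (4 adjusted over the list alone, camera adjusted p = 6.14e-08). It gave lower fat cell genes, with Cidec (-4.02 ± 0.80), Gpd1 (-3.96 ± 0.51), Plin1 (-3.03 ± 0.42) and Lipe (-1.77 ± 0.26), hormone-sensitive lipase. 17 of 25 adipocyte genes were lower (20 adjusted over the list alone, camera adjusted p = 4.06e-32). In all, 141 genes were higher and 248 lower with TBT. The total was 613 with the replicate block, 676 with only the arrays of the groups compared, 198 without pool 15, 143 without pool 19 and 81 without pool 20. LG268 against Rosi at day 1 went the same way, with Lgr5 (2.43 ± 0.43†), Apoc2 (2.39 ± 0.27), Cyp26b1 (2.10 ± 0.21) and Abca1 (1.74 ± 0.16) higher and Lgals12 (-3.52 ± 0.37), Adcy5 (-3.42 ± 0.24) and Plin1 (-3.29 ± 0.42) lower with LG268. 15 of 25 adipocyte genes were lower (19 adjusted over the list alone, camera adjusted p = 6.65e-25), and 5 of 17 LXR target genes were higher and 1 was lower (9 and 1 adjusted over the list alone, median 0.45, camera adjusted p = 1.99e-08). The counts were 504 higher and 539 lower. Counted otherwise, the total was 632 without pool 15, 512 without pool 19 and 349 without pool 20. The adjusted p passed the threshold with arrays left out for Cidec (0.0543 without pool 15).

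TBT and LG268 at day 1 gave 0 genes past limma's threshold, with 276 at an unadjusted p under 0.05 and a smallest adjusted p of 0.197; the replicate block gave 1 gene, and only the arrays of both groups gave 3. The 95% intervals of the log2 difference were from -0.54 to 0.11 for Abca1, from 5.03e-05 to 0.80 for Fabp4, from 0.18 to 0.90 for Angptl4 and from -4.10 to -0.88 for Cidec, none of which was called. Such a miss does not show that the 2 act alike. With no member called, camera called these lists higher with TBT (median, adjusted p; p past the threshold with a pool left out): fatty acid oxidation (0.07, 0.0269; 0.147, 0.111 and 0.0502 without pools 15, 12 and 19) and cell cycle (0.19, 1.35e-09). It called lower retinoid target (-0.15, 0.0429; 0.182, 0.0724 and 0.0647 without pools 19, 20 and 12), lipogenesis (-0.13, 0.016; 0.0673 without pool 20), osteoblast (-0.15, 0.0436; 0.158 and 0.138 without pools 15 and 19) and smooth muscle (-0.14, 0.0245; 0.14 without pool 19). With an estimated correlation these p were at least 0.315. The replicate block alone called LXR target (-0.13, 0.063, blocked 0.0288) and inflammation (-0.09, 0.102, blocked 0.0288) lower. By day 4 they differed, with Cox8b (2.85 ± 0.51†), Chchd10 (2.34 ± 0.35), Adig (2.26 ± 0.39) and Pnpla2 (1.06 ± 0.19) higher and Ndnf (-1.66 ± 0.49), Itga11 (-1.47 ± 0.30) and Lum (-1.27 ± 0.33), the matrix protein lumican, lower with TBT. 15 of 25 adipocyte genes were higher (22 adjusted over the list alone, camera adjusted p = 2.48e-28), and 12 of 24 fatty acid oxidation genes were higher (16 adjusted over the list alone, camera adjusted p = 3.92e-19). The counts were 380 higher and 119 lower. That total became 751 with the replicate block, 266 without pool 15, 39 without pool 19 and 11 without pool 20. Calls were lost with arrays left out, at the adjusted p given, for Cox8b (0.0579 without pool 20), Adig (0.0528 without pool 20), Ndnf (0.535, 0.337 and 0.0565 without pools 20, 19 and 12), Itga11 (0.147 and 0.126 without pools 20 and 19) and Lum (0.263, 0.251 and 0.092 without pools 19, 20 and 15).

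At day 4, the largest falls with TBT against Rosi were Elovl3 (-6.66 ± 0.53†), Cyp2e1 (-5.86 ± 0.32†), Tmem45b (-5.72 ± 0.42†), Sptlc3 (-5.04 ± 0.52) and Pck1 (-4.21 ± 0.37), a glycerol-forming enzyme. 8 of 16 thermogenic genes were lower (8 adjusted over the list alone, camera adjusted p = 1.36e-05, adjusted p = 0.141 with an estimated correlation), and 24 of 24 respiratory chain genes were lower (24 adjusted over the list alone, camera adjusted p = 1.5e-16, adjusted p = 0.141 with an estimated correlation). Macrophage genes were higher, with Mpeg1 (1.34 ± 0.14) and Marco (2.82 ± 0.38), as were Pdgfra (1.97 ± 0.19) and Cd5l (2.99 ± 0.65). 20 of 23 macrophage genes were higher (21 adjusted over the list alone, camera adjusted p = 1.92e-10, adjusted p = 0.141 with an estimated correlation). In all, 2993 genes were higher and 2688 lower. LG268 was further from Rosi, with Sptlc3 (-7.33 ± 0.52†), Elovl3 (-7.12 ± 0.53†), Cox8b (-5.57 ± 0.51†) and Lipe (-2.79 ± 0.26) lower and Marco (3.61 ± 0.38), Apod (3.58 ± 0.23), P2rx2 (3.36 ± 0.39†) and Omd (3.03 ± 0.51) higher. 24 of 25 adipocyte genes were lower (24 adjusted over the list alone, camera adjusted p = 1.42e-14, adjusted p = 0.139 with an estimated correlation), and 11 of 16 osteoblast genes were higher (11 adjusted over the list alone, camera adjusted p = 0.00135, adjusted p = 0.524 with an estimated correlation). The counts were 3928 higher and 3201 lower.

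TPhP at day 1 gave lower fat cell genes than Rosi, with Plin1 (-2.97 ± 0.42), Gpd1 (-2.96 ± 0.51), Aldh1a7 (-3.11 ± 0.50) and Pnpla2 (-1.29 ± 0.19), and higher Map3k7cl (1.37 ± 0.20) and Ccn2 (1.34 ± 0.27), a matrix-inducing factor. 16 of 25 adipocyte genes were lower (19 adjusted over the list alone, camera adjusted p = 1.37e-30). The counts were 89 higher and 257 lower. This count was 183 without pool 12, 134 without pool 19, 97 without pool 20 and 179 without the TPhP arrays of pool 12. MEHP at day 1 showed the same order, with Plin1 (-2.56 ± 0.42), Adcy5 (-3.04 ± 0.24) and Lgals12 (-2.69 ± 0.37) lower and Map3k7cl (1.52 ± 0.20) higher than with Rosi. 14 of 25 adipocyte genes were lower (19 adjusted over the list alone, camera adjusted p = 2.38e-24, adjusted p = 0.0781 with an estimated correlation). The counts were 74 and 206. Other fits gave a total of 478 with the replicate block, 630 with only the arrays of the groups compared, 136 without pool 15, 109 without pool 19 and 69 without pool 20. At day 4, TPhP gave lower Elovl3 (-5.36 ± 0.53), Cyp2e1 (-4.36 ± 0.32) and Cidea (-3.24 ± 0.48), a brown fat droplet protein, and higher Abi3bp (2.11 ± 0.42) and Phex (1.98 ± 0.49), a bone peptidase. 21 of 24 fatty acid oxidation genes were lower (21 adjusted over the list alone, camera adjusted p = 3.31e-13, adjusted p = 0.152 with an estimated correlation), and 24 of 24 cell cycle genes were higher (24 adjusted over the list alone, camera adjusted p = 2.81e-18, adjusted p = 0.177 with an estimated correlation). The counts were 2251 higher and 1956 lower. The number of changed genes was 704 with only the arrays of the groups compared and 2278 without pool 20. MEHP at day 4 gave lower Cyp2e1 (-4.18 ± 0.32), Elovl3 (-3.83 ± 0.53), Scd3 (-2.60 ± 0.40) and Pck1 (-2.57 ± 0.37) and higher Marco (2.20 ± 0.38) and Siglec1 (1.07 ± 0.15), macrophage receptors. 20 of 23 macrophage genes were higher (21 adjusted over the list alone, camera adjusted p = 4.61e-14, adjusted p = 0.228 with an estimated correlation). The counts were 1902 and 1995. The total was 354 with only the arrays of the groups compared and 1951 without pool 20. Fewer arrays ended the call, at the adjusted p given, of Ccn2 (0.0687 without pool 20).

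The last comparisons test whether each signed difference from vehicle changed from day 1 to day 4. A drop may be a deeper fall, as for Alpl with TBT. For Rosi it grew for Elovl3 (6.75 ± 0.75), Cox8b (6.11 ± 0.73), Cyp2e1 (5.91 ± 0.45) and Cidea (4.86 ± 0.68) and dropped for P2rx2 (-3.37 ± 0.56) and Mmp13 (-2.89 ± 0.55), a collagenase. 9 of 16 thermogenic genes were higher (9 adjusted over the list alone, camera adjusted p = 2.34e-06, adjusted p = 0.139 with an estimated correlation). In all, 2149 genes were higher and 2331 lower (total 2704 without pool 19 and 2406 without pool 20). For LG268 it grew for Cldn11 (2.71 ± 0.35), Apod (2.43 ± 0.33), a lipid carrier, and Moxd1 (2.87 ± 0.44), with 12 genes higher and 0 lower, against 7 and 1 after cyclic loess. That total became 32 with the replicate block, 45 without pool 12, 5 without pool 19 and 2 without pool 20. With TBT it grew for Thrsp (4.07 ± 1.00), Ppp1r1a (3.46 ± 0.57) and Slc2a4 (3.43 ± 0.54), the insulin-responsive glucose transporter, and dropped for Alpl (-1.62 ± 0.39). 11 of 19 lipogenesis genes were higher (16 adjusted over the list alone, camera adjusted p = 4.14e-21). The counts were 205 higher and 59 lower, against 150 and 72 after cyclic loess. This count was 621 with the replicate block, 630 without pool 12, 94 without pool 15, 20 without pool 19 and 23 without pool 20. With TPhP it grew for Adig (3.59 ± 0.56), a fat cell protein, Tshr (3.48 ± 0.54) and Srebf1 (1.60 ± 0.28) and dropped for Ctsk (-1.74 ± 0.40). The counts were 545 higher and 124 lower. Other fits gave a total of 1062 with the replicate block, 275 with only the arrays of the groups compared, 1360 without pool 12, 76 without pool 19, 85 without pool 20 and 1056 without the TPhP arrays of pool 12. With MEHP it grew for Cox8b (4.21 ± 0.73), Sptlc3 (4.17 ± 0.74) and Orm1 (3.67 ± 0.65), an acute-phase protein, and dropped for Fmod (-2.35 ± 0.43), fibromodulin. 17 of 25 adipocyte genes were higher (22 adjusted over the list alone, camera adjusted p = 5.04e-23). The counts were 640 higher and 309 lower. Their total was 376 with only the arrays of the groups compared, 1584 without pool 12, 78 without pool 19 and 93 without pool 20. Limma's call ended with fewer arrays, at the adjusted p given, for Moxd1 (0.0867 without pool 20), Thrsp (0.263 and 0.128 without pools 19 and 15), Alpl (0.343, 0.319 and 0.0889 without pools 20, 19 and 15), Ctsk (0.193 without pool 20) and Fmod (0.0814 without pool 19).

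The differences from vehicle were also compared between chemicals across the 14911 genes, which are not independent replicates, as 20 pairs. All pairs share the 4 vehicle arrays of a day. Sharing alone gave a mean correlation of 0.538 and covariance of 0.0145 (highest 0.0422) in 100 simulations without effects. The same simulations served both days, so their range is rough. At day 4, TPhP and MEHP had the highest correlation, 0.938 (covariance 0.2). With the vehicle arrays split 2 and 2 their covariance was 0.143 to 0.19, and their mean correlation of 0.735 lay below that of Rosi with MEHP (0.757) and with TPhP (0.743). TPhP and MEHP had 1434 common rises, against 198 if the calls were independent, and 976 falls, against 138. Rosi went with MEHP at 0.886 (covariance 0.319) and with TPhP at 0.884 (0.292), with 1689 and 1570 common rises against 386 and 349. LG268 went with TBT at 0.814 (covariance 0.12, split 0.062 to 0.109), with 484 common rises against 66.8. Rosi and LG268 had a correlation of 0.379 (covariance 0.0933, split 0.0354 to 0.0827), and 174 genes called in both had opposite signs. At day 1, LG268 and TBT had 0.757 (covariance 0.0276, split 0.00959 to 0.0215), within the range simulated, and 25 of the 34 LG268 rises were among the 74 of TBT, against 0.169. All 27 TPhP rises were among the 621 of Rosi, against 1.12, at a correlation of 0.664, within the range simulated (highest 0.832). At day 1 the covariances of Rosi with TPhP (0.0424, split 0.0243 to 0.0363), TBT (0.0431, split 0.0251 to 0.037) and MEHP (0.0487, split 0.0306 to 0.0425) lay above the highest simulated. Counts for independent calls leave out the shared vehicle arrays, so an excess over them does not show a shared effect.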

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

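The 8 tests of 3 patterns were chosen only after the result was seen, and the counts of other splits were planned. The TPhP arrays of pool 12 stood apart at both days. An exchange of labels between the days is argued against, since the higher of the 2 correlations across genes with the other day's profile was -0.16. So is one at day 1, where each of the other 5 arrays of that pool matched its own profile in the other pools better than the TPhP profile, by a correlation of at least 0.0878 (the TPhP array matched TBT, 0.565, MEHP, 0.554, and LG268, 0.523, better than TPhP, 0.471), and one at day 4 with the vehicle, Rosi, LG268 or TBT array (at least 0.191). One at day 4 with the MEHP array stays open and those 2 labels cannot be told apart, since the MEHP array matched TPhP (0.592) better than MEHP (0.542, a margin of -0.0497), and the TPhP array of that day matched MEHP (0.211), TBT (0.256) and Rosi (0.353) no worse than TPhP (0.208). Fewer neutrophils in the day 4 culture may account for part of the pattern: all 15 of 15 neutrophil genes were lower on it than on each of the other 3 arrays, by a median log2 of -1.93, and the median of the list against vehicle was -0.49, or 0.65 (adjusted p = 0.00794) without pool 12.

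Macrophage genes were lower with Rosi at day 4. Dilution by RNA of other cells would lower endothelial genes alike, yet their change was higher by a mean of 1.58 (SD 1.16, n = 4). By pool it was 2.56 (12), -0.094 (15), 1.85 (19) and 1.98 (20). Without pool 15, whose Rosi array stood apart, the mean was 2.13 (SD 0.377, n = 3). Endothelial genes rose that day with LG268 and TBT, and a rise may hide dilution in any pool. Dilution and fewer macrophages (untested) cannot be told apart.

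TPhP and MEHP changed genes alike at day 4. The shared vehicle arrays are argued against as the whole of it. With different vehicle arrays on both sides the covariance was at least 0.143. Without each pool the correlation was at least 0.897, but shared vehicle arrays raise it. A single pool stays open. A response shared by the 2 chemicals remains a hypothesis, found and tested on the same data.

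In 51 of 702 sets of 4 arrays of a key gene or list score, 1 array lay far from the other 3, by a ratio of its gap to the range above Dixon's 95% critical value; chance gives about 1 in 20, or 35.1. The array was the lowest of 4 unless called highest. For pool 15 the ratios were, in Rosi day 4 Lpl (0.86), Pparg (0.836), Abcg1 (0.871, highest), Tgm2 (0.857, highest), the adipocyte score (0.892), the cholesterol synthesis score (0.952), the lipogenesis score (0.933), the megakaryocyte score (0.835), the glucocorticoid score (0.897, highest), the interferon score (0.900, highest) and the peroxisome score (1), in Rosi day 1 Angptl4 (0.856), Ibsp (0.973, highest), the osteoblast score (0.929, highest) and the glucocorticoid score (0.915, highest) and in TPhP day 4 Tgm2 (0.932, highest) and the ER stress score (0.832). Pool 15 also stood apart in TBT day 1 Ibsp (0.938, highest), the chondrocyte score (0.981, highest), the mast cell and basophil score (0.953, highest) and the glucocorticoid score (0.942, highest), in TBT day 4 the cholesterol synthesis score (0.832) and in TPhP day 1 the stromal progenitor score (0.892, highest) and the glucocorticoid score (0.844, highest). Further values of pool 15 were, in MEHP day 1 the neutrophil score (0.900, highest), in LG268 day 4 the cell cycle score (0.841) and in vehicle day 1 the glucocorticoid score (0.882, highest). For pool 12 they were, in LG268 day 4 Fabp4 (0.88) and the stromal progenitor score (0.957), in TPhP day 1 Plin1 (0.843), the cholesterol synthesis score (0.933), the macrophage score (0.841) and the ER stress score (0.862, highest) and in vehicle day 4 Adipoq (0.953), the cholesterol synthesis score (0.898) and the megakaryocyte score (0.892). Pool 12 also stood apart in vehicle day 1 Angptl4 (0.848) and the chondrocyte score (0.835), in TPhP day 4 Acp5 (0.906) and the B cell score (0.939) and in TBT day 1 the lipogenesis score (0.8292). Further values of pool 12 were, in Rosi day 1 the matrix score (0.87) and the B cell score (0.948, highest), in LG268 day 1 the B cell score (0.908, highest) and the T and NK cell score (0.869, highest) and in MEHP day 1 the B cell score (0.868, highest). Pools 19 and 20 gave Adipoq in LG268 day 1 (0.882, pool 19), the adipocyte score in Rosi day 1 (0.918, pool 19), the cholesterol synthesis score in vehicle day 1 (0.848, pool 19), Angptl4 in naive (0.856, highest, pool 20) and the thermogenic score in MEHP day 1 (0.864, highest, pool 20).

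The difference from vehicle differed between day 4 and day 1, by limma's interaction term, for 4480 genes with Rosi, 12 genes with LG268, 264 genes with TBT, 669 genes with TPhP and 949 genes with MEHP. Regrouping the 16 arrays at random 100 times, the real grouping included, gave counts as large in 2 for Rosi (highest other 4648), 9 for LG268 (highest other 601), 11 for TBT (highest other 1921), 8 for TPhP (highest other 3209) and 8 for MEHP (highest other 3700). These regroupings mix days and treatments, so their counts hold that structure of the samples and cannot test chance. With only the day labels exchanged within pools, the highest other counts were 121, 0, 0, 185 and 0 in the same order. Those 8 groupings are too few for a share under 0.05, so chance was not excluded for any chemical.

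For each comparison of 2 groups, the 35 splits of the 8 arrays into 4 and 4 were counted, of which 27 keep both arrays of at least 1 pool together and 8, the real one included, part all 4 pools. Brackets give the real count, the highest other and the highest other of the 8. Over the 35, which ignore the pools, only the real split was as large, a share under 0.05, for vehicle day 1 against naive (2642, 638, 61), vehicle day 4 against naive (4308, 2177, 2177), vehicle day 4 against day 1 (1922, 306, 134), Rosi day 1 (1081, 1, 0), LG268 day 1 (36, 1, 0), TBT day 1 (81, 0, 0), TPhP day 1 (32, 0, 0), MEHP day 1 (78, 0, 0), Rosi day 4 (7316, 5528, 4530), LG268 day 4 (965, 465, 20), TBT day 4 (2990, 1168, 711), TPhP day 4 (2818, 2380, 2380), MEHP day 4 (3548, 2700, 1884), TBT against Rosi day 1 (389, 3, 0), LG268 against Rosi day 1 (1043, 3, 0), TPhP against Rosi day 1 (346, 1, 1), MEHP against Rosi day 1 (280, 1, 1), TBT against Rosi day 4 (5681, 4361, 2267), TBT against LG268 day 4 (499, 87, 0) and LG268 against Rosi day 4 (7129, 4439, 3924). The 8 keep to the pools but are too few for a share under 0.05, and no allowance was made for the number of comparisons. So these counts do not exclude chance for any comparison. For LG268 and MEHP at day 4 the highest other split was that of pools 12 and 15 against 19 and 20, and the replicate block gave 1590 and 4230 genes. Over the 35 the share was not under 0.05 for TPhP against Rosi day 4 (4207, 4703, 310, with 2 of 35 as large) and for MEHP against Rosi day 4 (3897, 5491, 267, with 3 of 35 as large). There the highest other split put Rosi arrays of pools 12, 19 and 20 with the pool 19 array of the other chemical. For TBT against LG268 day 1 the real count of 0 makes all 35 of 35 splits as large (highest other 0), so nothing can be said of chance.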

How the results depend on the processing

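The alternatives without the TPhP arrays of pool 12 and without the day 4 Rosi array of pool 15 were chosen after seeing the data. Of 291 counts under an alternative, 199 lay within 1.5 times the count reported. Cyclic loess between arrays, the mean of all probe sets of a gene, no filter and a stricter filter moved none of the 28 counts further. With the replicate block the totals were 32 for LG268 between days, 621 for TBT between days, 1062 for TPhP between days, 68 for LG268 day 1, 1590 for LG268 day 4, 478 for MEHP against Rosi day 1, 176 for MEHP day 1, 1 for TBT against LG268 day 1, 613 for TBT against Rosi day 1, 171 for TBT day 1, 751 for TBT against LG268 day 4 and 71 for TPhP day 1, and it ended none of the 1800 calls of named genes and added 244 of 2290. With only the arrays of the groups compared, which are fewer, day 1 totals rose for MEHP (190), TBT (174) and TBT against LG268 (3). Against Rosi they rose for MEHP (630) and TBT (676). Day 4 totals fell for LG268 (369), TBT (1676), TPhP (816), MEHP (1048), TPhP against Rosi (704) and MEHP against Rosi (354). So did those between days for MEHP (376) and TPhP (275) and of vehicle day 4 against naive (2093) and day 1 (568). SEs pool the spread of both days, and whether it differed by day was not tested. Without the TPhP arrays of pool 12, TPhP gave 1056 between days and 179 against Rosi day 1. The lowest and highest totals with arrays left out, a smaller sample, follow. Between days they were LG268 2 to 45, MEHP 78 to 1584, Rosi 2406 to 5106, TBT 20 to 630 and TPhP 76 to 1360. Against Rosi at day 1 they were LG268 349 to 1052, MEHP 69 to 249, TBT 81 to 400 and TPhP 97 to 251. Against Rosi at day 4 they were MEHP 1951 to 4807 and TPhP 2278 to 5111. At day 1 LG268 gave 13 to 38, MEHP 10 to 110, Rosi 430 to 1013, TBT 33 to 117 and TPhP 8 to 63. At day 4 LG268 gave 367 to 1005, MEHP 1503 to 3990, TBT 1306 to 3044 and TPhP 1082 to 3400. TBT against LG268 gave 0 to 1 at day 1 and 11 to 744 at day 4. Vehicle day 1 against naive gave 868 to 2878, day 4 against naive 2433 to 4874 and day 4 against day 1 785 to 1558. Some totals rose without pool 12, as for TBT between days (264 to 630), and others fell. Of the 1800 calls, 1625, 1506, 1234 and 1175 held without pools 12, 15, 19 and 20, 1333 with only the arrays compared, 1697 without a filter and 1729 after loess. Of 358 camera calls, 58 held with an estimated correlation, 224 by fry, which does not compare a list with other genes, and 356 with the replicate block, which added 18. Without pool 12, the camera direction turned for 65 list results called in neither fit and 5 called in at least 1, with a median log2 change (in brackets, its range with any pool or array left out) of 0.0201 for cholesterol synthesis in TPhP day 1 (adjusted p = 0.924; -0.181 to 0.0201), 0.65 for neutrophil in TPhP day 4 (adjusted p = 0.00794; -1.08 to 0.65), 0.143 for macrophage in TPhP against Rosi day 1 (adjusted p = 0.0486; -0.202 to 0.144), -0.396 for smooth muscle in LG268 between days (adjusted p = 0.0229; -0.396 to 0.0924) and 0.755 for T and NK cell in TPhP between days (adjusted p = 0.0212; -0.588 to 0.755). The correlations of the 11 of 20 pairs that moved by at least 1 SD of the values with a pool left out, with no filter on low values were, at day 1, LG268 and MEHP 0.582, LG268 and TBT 0.706, Rosi and MEHP 0.654, Rosi and TBT 0.614, TBT and MEHP 0.713, TBT and TPhP 0.68 and TPhP and MEHP 0.749, and at day 4, Rosi and MEHP 0.87, Rosi and TBT 0.701, Rosi and TPhP 0.867 and TPhP and MEHP 0.916. The correlations of all 20 pairs of chemicals with vehicle arrays split 2 and 2 were, at day 1, LG268 and MEHP 0.287, LG268 and TBT 0.395, LG268 and TPhP 0.171, Rosi and LG268 0.245, Rosi and MEHP 0.483, Rosi and TBT 0.432, Rosi and TPhP 0.445, TBT and MEHP 0.446, TBT and TPhP 0.386 and TPhP and MEHP 0.467, and at day 4, LG268 and MEHP 0.341, LG268 and TBT 0.565, LG268 and TPhP 0.298, Rosi and LG268 0.253, Rosi and MEHP 0.757, Rosi and TBT 0.592, Rosi and TPhP 0.743, TBT and MEHP 0.664, TBT and TPhP 0.628 and TPhP and MEHP 0.735. The cause of the moves given here was not tested. On arrays, signal over background limits what can be seen, and 7269 genes lay below the filter.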

Other observations

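The lists given here were chosen after their values were seen, and all their tests were planned. With LG268 at day 4, 1 of 8 mast cell and basophil genes fell (3 adjusted over the list alone, camera adjusted p = 0.00358, adjusted p = 0.355 with an estimated correlation), and 1 of 7 megakaryocyte genes fell (5 adjusted over the list alone, camera adjusted p = 0.000654, adjusted p = 0.24 with an estimated correlation). Of the vessel list, 4 of 14 endothelial genes rose (10 adjusted over the list alone, camera adjusted p = 2.53e-06, adjusted p = 0.297 with an estimated correlation). With TBT at day 4, 5 of 15 neutrophil genes fell (11 adjusted over the list alone, camera adjusted p = 0.000134, adjusted p = 0.344 with an estimated correlation), and 6 of 14 osteoclast genes fell (6 adjusted over the list alone, camera adjusted p = 0.000623). With Rosi at day 4, 3 of 10 chondrocyte genes rose and 5 fell (3 and 6 adjusted over the list alone, median -0.60, camera adjusted p = 0.324), and 6 of 15 inflammation genes fell (6 adjusted over the list alone, camera adjusted p = 0.0987). With MEHP at day 1, 0 of 15 inflammation genes passed limma's test (0 higher and 1 lower adjusted over the list alone, median -0.37, camera adjusted p = 0.0263, adjusted p = 0.647 with an estimated correlation). Leaving out arrays brought the adjusted p past the threshold for the mast cell and basophil list (0.0612 without pool 12) and the inflammation list (0.0603 and 0.0548 without pools 12 and 15). Of the red cell list only 3 genes passed the filter, with values for Rosi at day 4 of Epor (-0.07 ± 0.17, adjusted p = 0.749), the erythropoietin receptor, Slc4a1 (0.06 ± 0.17, adjusted p = 0.825) and Gata1 (-0.05 ± 0.13, adjusted p = 0.788).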
